A study of Caenorhabditis elegans with 2 samples.

How the data were processed

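The material was a pair of ChIP-seq replicates from L2 larvae of a C. elegans strain with an EGFP-tagged lin-13 transgene. Per the labels, libraries covered fragments of 150 to 350 bp, and the replicates are biological. Per the file listings deposited with the samples, peak lists exist for replicate 1, replicate 2 and the pooled replicates as input for the irreproducible discovery rate (IDR) step, and a thresholded list was derived from those 3 lists. Each was deposited on the ce10 and ce11 builds. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. A control experiment is named in the labels and was not analysed here.

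The deposited lists give a signal value per entry, on a scale that is not given in the sources used here. Signal was therefore used only to rank entries within a list, apart from a rank correlation of the replicates. The deposited lists also give a −log10 q value per entry, between 2.73 and 2.99 in the thresholded ce11 list, which was not used for selection. The p-value column of the deposited lists is unused. Each replicate list and the pooled list holds 30000 entries, so the number of entries says nothing about depth. The lists hold no read counts, the depth of each replicate is unknown, and no interval that needs depth is given. Intervals on shares are over peaks or genes and cover counting error only.

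All 3040 thresholded ce11 peaks were found entry for entry in the pooled list and were its 3040 entries of highest signal. In the thresholded list 7 intervals carry more than 1 summit, and each summit was kept as its own peak. Coordinates are 1-based on ce11. The reference was WBcel235 with Ensembl release 115 gene models, which has the chromosomes of ce11, and no ce11 entry ran past a chromosome end. The ce10 lists were compared only with each other, without annotation.

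The choices of test, promoter window, gene lists, motifs and alternatives were fixed before the data were examined. Overlap between lists required at least 1 bp. Overlaps and annotation shares of nuclear peaks were compared with 1000 circular shifts within chromosomes (two-sided permutation p, smallest value 0.001) and, for shares, with pooled entries overlapping no thresholded peak by Fisher's exact test. A summit in the promoter window of a protein-coding gene was counted as promoter, then coding exon, intron, other gene sequence and intergenic in that order. Soft-masked bases made up 35.7% of the nuclear reference. Gene lists were tested by Fisher's exact test and motifs by the exact McNemar test within 75 bp of the summit, with Benjamini-Hochberg adjustment over 18 lists and over 9 motif and GC tests, at a threshold of 0.05. A gene name of the heat shock list, daf-21, was unmatched, and 20 gene identifiers matched the others because some names are shared. Where a list had 0 members with a peak, the limit given is the upper bound of the exact 95% interval. A peak in the promoter windows of several genes was counted for each of them, and such sharing is stated where the gene is named.

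Genes were named by a fixed rule: lin-13 and unc-119, the protein-coding gene with the nearest start to each of the 20 strongest thresholded peaks, up to 4 members of each list with the highest promoter signal, and every synMuv B member with a promoter peak. As 13 of the 20 strongest peaks were mitochondrial, the rule was extended, after the values were seen, to the 20 strongest nuclear peaks. A promoter that the rule would name among the chemoreceptor genes is not reported here. Mitochondrial peaks were left out of the location, list and motif tests.

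The location, list and motif tests were tested on simulated data with planted answers. In 20 simulations each, a promoter excess was called 20 times when 50% of 3013 peaks were placed in promoters and the rest at random. A list with 50% of its members hit among 19973 genes was called 20 times, and a motif written into 10% of 3013 windows 20 times. There were 0 false calls among 20, 340 and 160 tests. Simulated peaks without a planted answer lay at random positions and genes were hit independently. The GC difference between real summits and their control windows was not simulated, so the 0 false calls do not cover it. Alternatives were the stronger 1520 peaks, each replicate's own strongest entries in place of the thresholded list, the strongest entries of the pooled list, other overlap rules, ce10 lists, other promoter windows, a background of genes with any pooled entry at the promoter, other motif windows and other locus distances. Leaving out mitochondrial peaks, keeping 1 summit per interval, giving each summit to the nearest start only, splitting motif tests by promoter, rearranging motifs, stratifying by GC content and scanning gene families were added after the data were seen. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.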

Results

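Chromatin immunoprecipitation followed by sequencing was used to map LIN-13 in Caenorhabditis elegans. LIN-13 is a zinc-finger protein of the synMuv B class, a set of chromatin regulators that hold back vulval fate. The strain, OP49, carried a lin-13 transgene tagged with TY1, EGFP and FLAG together with an unc-119 marker. Whole larvae of mixed sex at the L2 stage formed 1 group with 2 replicates, which the labels number as biological replicates 1 and 2. The design has no other group, so the questions addressed are where the protein was enriched and how far the replicates shared those sites. Each replicate list held 30000 entries and the thresholded list held 3040 peaks on ce11, of which 3013 lay on nuclear chromosomes and 27 on the mitochondrial chromosome. The lists carry no read counts, so the depth is unknown.

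Which sites recurred between replicates was asked first. The strongest nuclear peak lay upstream of rpl-3, a large-subunit ribosomal protein gene (WBGene00004414), at III:3867359-3867758 on ce11. It ranked 2 of 30000 by deposited signal in replicate 1 and 7 in replicate 2. The peak upstream of cdc-48.1 (WBGene00007352), which encodes a AAA-type ATPase, at II:10563410-10563731 ranked 4 and 12 in the same lists. The peak upstream of tasp-1 (WBGene00010480), at III:10759068-10759413 and also in the promoter window of K01G5.10, ranked 3 and 15.

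Of the 3040 thresholded peaks, 2515 (82.7%, Wilson 95% interval 81.3 to 84.0) overlapped by at least 1 bp an entry among the 3040 strongest of replicate 1. For replicate 2 the count was 2649 (87.1%, interval 85.9 to 88.3), and 2183 peaks (71.8%) overlapped such entries in both. Against the full lists, 3014 peaks overlapped an entry of replicate 1 and 3012 an entry of replicate 2. Among nuclear peaks, 2507 overlapped the strongest entries of replicate 1, against a mean of 61.9 (SD 7.88) after circular shifts, and 2622 overlapped those of replicate 2, against 61.5 (SD 7.66). Each two-sided permutation p was 0.001, the smallest that 1000 shifts can give. The thresholded list was made from the same replicates, so these overlaps are not independent of it. Compared directly, 2224 of the 3040 strongest entries of replicate 1 (73.2%) overlapped one of the 3040 strongest of replicate 2. Over the 2986 peaks with an entry in both replicates, signal correlated with Spearman rho = 0.70 (95% bootstrap interval 0.67 to 0.72), across peaks, which are not independent replicates.

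**Figure D1:**
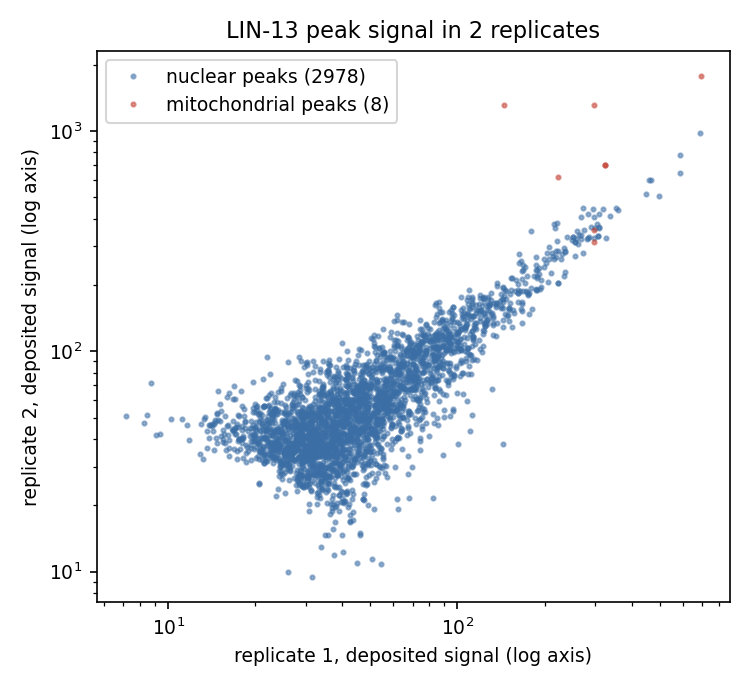
Deposited signal of the strongest overlapping entry in replicate 1 (x axis, log scale) and replicate 2 (y axis, log scale) for each thresholded peak, in the units of the deposited lists. The 2978 nuclear peaks (blue) rise along the diagonal with more scatter at low signal, and the 8 mitochondrial peaks found in both replicates (red) include points above that band.

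The locus of the tagged protein carried strong peaks. Upstream of lin-13 (WBGene00003002, III:7700338-7709491, minus strand), the strongest entry lay at III:7710120-7710443 with its summit 786 bp upstream of the annotated start. It ranked 12 in replicate 1, 55 in replicate 2 and 41 in the pooled list. Further thresholded peaks had summits at 7711083 (pooled rank 153) and 7712113 (pooled rank 945), the latter just before the start of C03B8.3 at 7712309. Inside the lin-13 gene itself, 0 pooled entries were listed. At unc-119 (WBGene00006843, III:10902641-10908935, plus strand), the C. elegans gene of the name given for the marker, the strongest entry within 5000 bp ranked 1970 in replicate 1, 2461 in replicate 2 and 2255 in the pooled list. It lay in an intron at III:10905203-10905552, and its summit was 2737 bp downstream of the start. The labels do not say from which species the marker sequence came. These ranks have no test, and the lists cannot separate endogenous sequence from transgene copies.

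**Figure D2:**
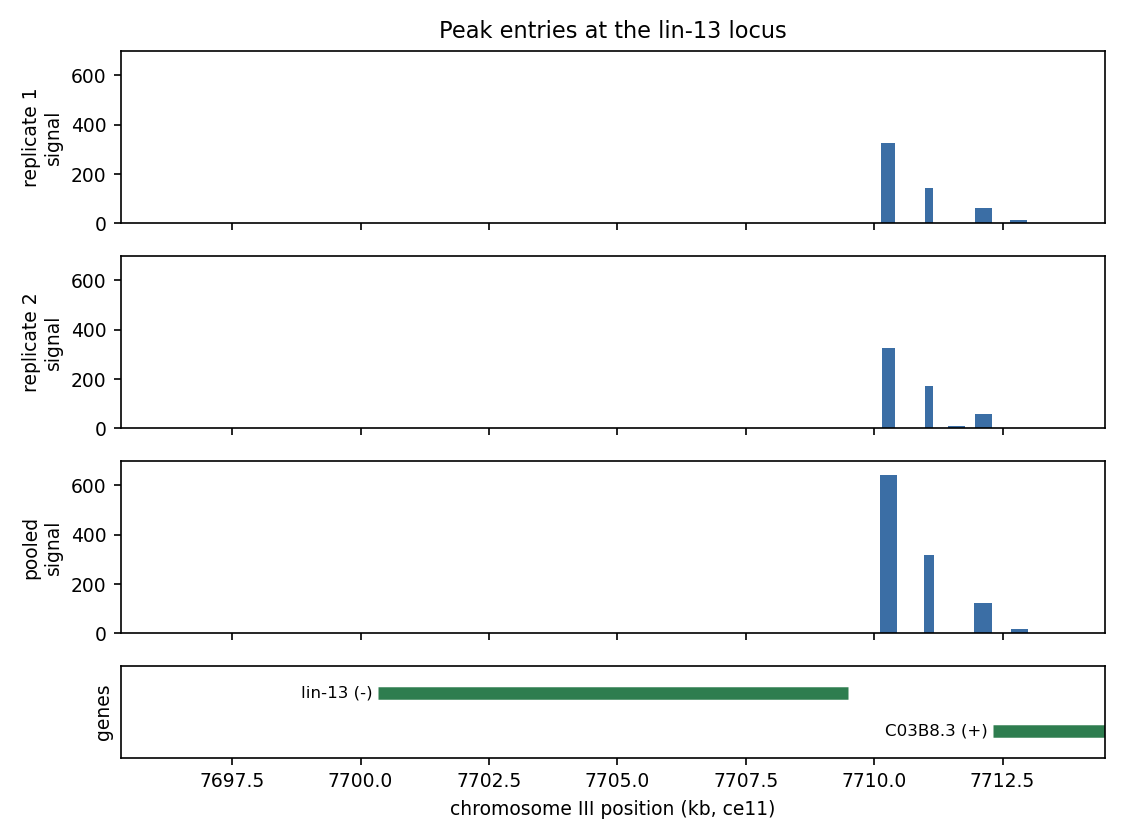
Peak entries within 5000 bp of lin-13 on chromosome III (x axis, kb, ce11), with deposited signal on the y axis for replicate 1, replicate 2 and the pooled list, above the annotated genes. All entries lie upstream of lin-13, the highest with a summit 786 bp from its start.

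The location of the nuclear peaks relative to genes was compared with circularly shifted positions. Promoters, defined as 1000 bp upstream to 200 bp downstream of an annotated protein-coding start, held 1727 of 3013 summits (57.3%), against 21.1% (SD 0.774) after shifts. Coding exons held 29 summits (0.962%), against 20.2% (SD 0.733). Introns held 17.7%, against 31.2% (SD 0.912), and intergenic sequence held 18.9%, against 21.2% (SD 0.775). UTRs and non-coding genes held 5.18%, against 6.26% (SD 0.466). The two-sided permutation p was 0.001, the smallest that 1000 shifts can give, for promoters, coding exons and introns, 0.003 for intergenic sequence and 0.02 for UTRs and non-coding genes. The last of these calls was lost in the strongest entries of replicate 2 alone (5.81%, permutation p = 0.3337). Each summit had 1 class and promoters were assigned first, so the promoter excess by itself lowers the other shares. The lower shares of introns, intergenic sequence, and UTRs and non-coding genes are therefore no separate evidence of avoidance. Shares among only the summits outside promoters were not tested. Relative to the 26572 pooled entries that overlapped no thresholded peak, of which 22.9% lay in promoters, the promoter odds ratio was 4.53 (95% interval 4.19 to 4.90, Fisher's exact test). Of those entries 6.10% lay in coding exons, 38.6% in introns and 25.8% in intergenic sequence. The coding exon deficit was thus smaller against them than against shifts (odds ratio 0.150, interval 0.0997 to 0.216).

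**Figure D3:**
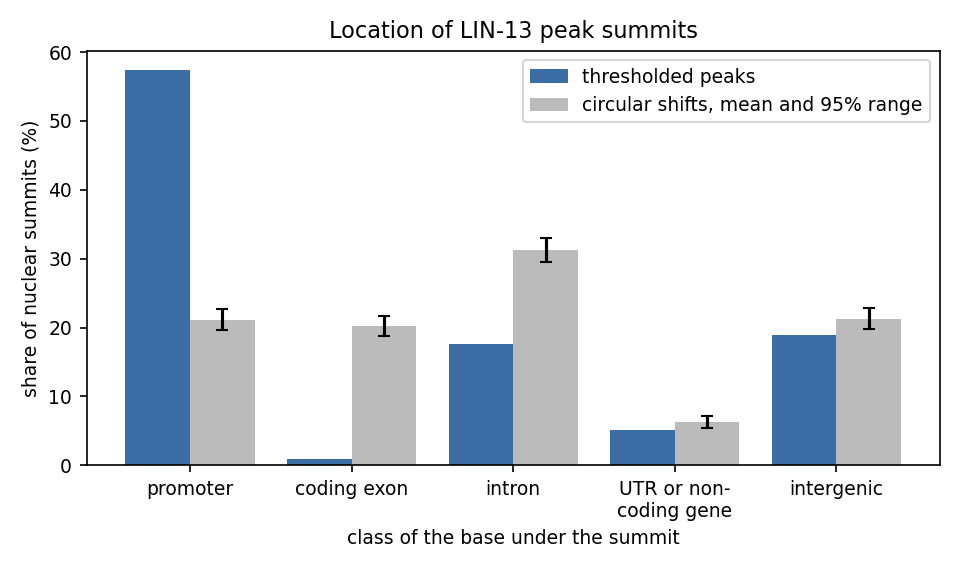
Share of nuclear peak summits (y axis, %) in each annotation class (x axis) for the 3013 thresholded peaks (blue) and for 1000 circular shifts (grey, mean with the central 95% range). Promoters held 57.3% of summits against 21.1% after shifts, and coding exons held 0.962% against 20.2%.

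Summits clustered upstream of gene starts. Of the 3013 nuclear summits, 2154 (71.5%) lay upstream of the nearest protein-coding start, at a median upstream distance of 300.5 bp. The fullest 100 bp bin, 100 to 200 bp upstream, held 465 summits, and 230 summits lay over 5000 bp from any protein-coding start. The outermost annotated start of each such gene was used, and starts of non-coding genes were not considered. Among the 20 strongest nuclear peaks, those at cox-5A (a subunit of cytochrome c oxidase; III:12905062-12905331), hsr-9 (I:9625937-9626220, also in the promoter window of rps-19) and puf-9 (a Pumilio-family RNA-binding protein; X:5841173-5841443) had summits 295, 172 and 281 bp upstream of the start. Others lay farther off, such as X:11093893-11094439, whose nearest start was that of W02H3.3 at 3985 bp and which ranked 8 in replicate 1 and 21 in replicate 2.

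**Figure D4:**
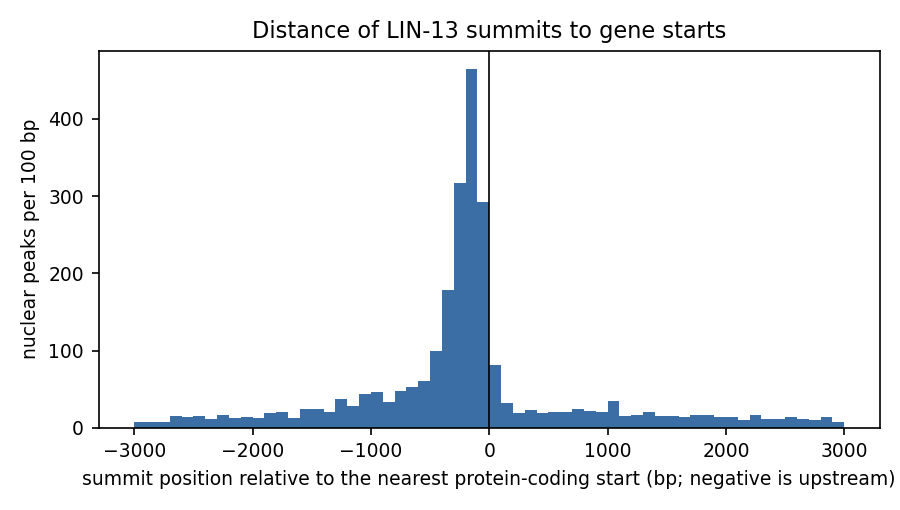
Number of nuclear summits per 100 bp bin (y axis) by position relative to the nearest protein-coding start (x axis, bp, negative values upstream). The bin 100 to 200 bp upstream holds 465 summits, the most of any bin.

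The distribution over chromosomes differed. Chromosome III carried 606 peaks, or 44.0 per Mb, and chromosome V carried 420, or 20.1 per Mb. The pooled entries outside thresholded peaks were also denser on III, with 4568 there and 4210 on the longer V. This contrast was not tested. On X there were 500 peaks, which was 16.6% of nuclear peaks against 18.6% of the pooled entries outside thresholded peaks (odds ratio 0.870, 95% interval 0.785 to 0.963, two-sided Fisher's exact p = 0.00685). Autosomal arms, the outer 30% at each end, held 51.9% of autosomal peaks against 53.9% of those entries (odds ratio 0.923, interval 0.849 to 1.00, two-sided Fisher's exact p = 0.06). By chromosome, odds ratios ran from 0.770 on III (54.5% against 60.8%, interval 0.647 to 0.917) to 1.11 on I (53.6% against 50.95%, interval 0.928 to 1.33). Only on III did the interval exclude equal shares, and these intervals were not adjusted for the number of chromosomes. In the strongest entries of replicate 2 alone the arm share was 50.7% against 54.2% of that replicate's other entries (odds ratio 0.870, Fisher's exact p = 0.00103), whereas in those of replicate 1 alone it was 51.4% against 52.1% (odds ratio 0.972, p = 0.5003). Soft-masked bases made up at least 50% of the sequence within 100 bp of 477 summits (15.8%). The share was 27.9% (SD 1.01) after shifts (two-sided permutation p = 0.001, the smallest possible) and 34.1% among the other pooled entries. When any masked base counted, the shares were 88.98% at summits and 89.8% after shifts, and the shift permutation test gave p = 0.1489. That summit share stayed below the 95.1% of the other pooled entries (odds ratio 0.419, interval 0.368 to 0.477, Fisher's exact p = 8.07e-36). Masked bases were not matched to repeat elements and GC content was not adjusted for. A deficit at repeat elements was therefore not tested.

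Promoter peaks were then counted over gene lists fixed beforehand. Of 19973 nuclear protein-coding genes, 2312 (11.6%) had a thresholded summit in the promoter window, and 18 lists were tested against all other genes by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the lists. Ribosomal protein genes had the highest share, with 65 of 76 members (85.5%, exact 95% interval 75.6 to 92.5; odds ratio 46.4, interval 24.3 to 97.7, p = 9.47e-50, adjusted p = 1.70e-48). Besides rpl-3, the strongest were rpl-15 (IV:654765-655068, pooled rank 13, a peak shared with K11H12.8), rpl-20 (IV:4749914-4750237, rank 14, shared with Y17G9B.5) and rpl-35 (III:7854545-7854836, rank 16). When each summit was given only to the gene with the nearest start, an alternative chosen after the data were seen, 39 of 76 members kept a peak (odds ratio 11.8, exact adjusted p = 1.69e-21).

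SynMuv B, DREAM complex and heterochromatin genes had peaks at 9 of 19 members (47.4%, exact 95% interval 24.4 to 71.1; odds ratio 6.90, interval 2.48 to 18.9, p = 0.000114, adjusted p = 0.000686). Besides lin-13 these were lin-54 (pooled rank 46), which encodes the DNA-binding subunit of DREAM, lin-9 (rank 73), the histone-binding protein gene lin-53 (rank 126), the E2F gene efl-1 (rank 194), the Retinoblastoma gene lin-35 (rank 257), lin-36 (rank 466), lin-52 (rank 2706) and the DP gene dpl-1 (rank 2785). Some of these peaks also lay in the promoter window of another gene: rpl-12 for lin-54, nra-2 for lin-53, fbxa-90 for efl-1 and vps-51 for lin-35. The peak of lin-35 lay at I:5807438-5807612 with its summit 194 bp upstream, and that of efl-1 at V:16965747-16965923 with its summit 179 bp upstream. The dpl-1 peak ranked 4214 in replicate 1 and 2581 in replicate 2. The members without a promoter peak were lin-15B, lin-37, lin-61, hpl-1, hpl-2, met-2, let-418, tam-1, lin-65 and arle-14. The parts of the list were not tested apart, so its enrichment does not show one for heterochromatin genes. SynMuv A genes had a peak at 1 of 4 members, lin-38 (rank 173, shared with mrpl-37; exact p = 0.389, adjusted p = 0.4997), and the vulval induction list at 1 of 16, lin-7 (rank 376, shared with elof-1 and Y54G11A.17; adjusted p = 1). Among only the 7260 genes with any pooled entry in the promoter window, 9 of 15 synMuv B members had a thresholded peak and the call was lost (odds ratio 3.22, exact adjusted p = 0.0931). The tagged locus lin-13, where transgene copies cannot be separated, counted as a synMuv B member with a peak. No test was made without it.

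Cell cycle and DNA replication genes had peaks at 12 of 36 members (33.3%; odds ratio 3.83, 95% interval 1.74 to 7.98, exact p = 0.000487, adjusted p = 0.00175). The strongest were at pcn-1, which encodes the sliding clamp PCNA (pooled rank 327), the replicative helicase gene mcm-4 (rank 472), the centriole gene sas-4 (rank 650, shared with F10E9.11) and the cyclin E gene cye-1 (rank 934, shared with pqn-21). Heat shock and stress genes had peaks at 7 of 20 members (35.0%; odds ratio 4.12, interval 1.39 to 11.1, exact p = 0.00545, adjusted p = 0.0164), led by the chaperone genes hsp-60 (rank 57, shared with Y22D7AL.10), hsp-1 (rank 140), hsp-3 (rank 204) and hsp-6 (rank 609, shared with C37H5.5). Histone genes had peaks at 16 of 72 members (22.2%; odds ratio 2.19, interval 1.17 to 3.88, exact p = 0.00877, adjusted p = 0.0226), among them his-37 (rank 60), his-67 and his-68 (rank 240, a peak shared also with alg-5) and the H3.3 gene his-72 (rank 713). Histone genes include near-identical copies and shared divergent promoters, so their count is uncertain. The cell cycle, heat shock and histone calls were each lost with the stronger 1520 peaks (odds ratios 2.67, 3.34 and 1.91, exact adjusted p = 0.105, 0.105 and 0.194) and with the nearest start only (odds ratios 2.65, 2.75 and 1.77, exact adjusted p = 0.0985, 0.206 and 0.291). The histone call was also lost in replicate 1 alone (odds ratio 1.86, exact adjusted p = 0.106) and in the window of 2000 bp upstream to 500 bp downstream (1.90, adjusted p = 0.0657). Among genes with a pooled entry at the promoter it held, with 16 of 20 histone genes (odds ratio 8.61, exact adjusted p = 7.64e-05). The heat shock call was also lost among genes with a pooled entry at the promoter (odds ratio 1.88, exact adjusted p = 0.400).

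Chemoreceptor genes carried few peaks, at 11 of 1171 members (0.939%; odds ratio 0.0680, 95% interval 0.0338 to 0.122, exact p = 3.21e-48, adjusted p = 2.89e-47), including sri-5 (pooled rank 258, shared with rsr-1) and srr-10 (rank 1293, shared with clic-1). Cuticle collagen genes had peaks at 5 of 156 members (3.21%; odds ratio 0.251, interval 0.0804 to 0.601, exact p = 0.000351, adjusted p = 0.00158), including col-38 (rank 344, a peak shared with the ribosomal protein gene rpl-5) and col-71 (rank 685, shared with Y49F6B.2), and col-63 (rank 1096) and col-185 (rank 1768), whose peaks lay in no other promoter window. The collagen call was lost among genes with a pooled entry at the promoter (odds ratio 0.395, exact adjusted p = 0.145), where that of chemoreceptors held (odds ratio 0.252, adjusted p = 5.27e-06). Homeobox genes had peaks at 3 of 80 members, ceh-38 (rank 128, shared with malt-1), ceh-92 (rank 2137, shared with Y66D12A.7) and ceh-20 (rank 2184), and missed the threshold (odds ratio 0.297, exact p = 0.0224, adjusted p = 0.0503). With the window of 500 bp upstream to 100 bp downstream the homeobox list passed it (1 of 80, exact adjusted p = 0.0160), as it did with 2000 bp upstream to 500 bp downstream (4 of 80, adjusted p = 0.0277). The ceh-92 peak ranked 3662 in replicate 1 and 1901 in replicate 2, and the ceh-20 peak ranked 1244 and 4557.

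GC content differed between promoters with and without peaks, and odds ratios among genes with a pooled entry at the promoter were therefore also stratified by GC tercile, a step added after the data were seen. They were 11.6 for ribosomal proteins (95% interval 4.68 to 28.6), 13.3 for histones (2.18 to 81.5), 3.88 for cell cycle genes (1.21 to 12.4) and 0.330 for chemoreceptors (0.165 to 0.659). The intervals for synMuv B genes (2.76, 0.797 to 9.56), heat shock genes (1.44, 0.460 to 4.50) and cuticle collagens (0.510, 0.164 to 1.59) included 1.

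The tissue, germline and dosage compensation lists did not pass the threshold. The muscle list had 0 of 18 members with a peak (exact 95% upper limit 18.5%), the epidermis and cuticle patterning list 0 of 18 (18.5%) and the intestine list 0 of 17 (19.5%), with an exact adjusted p of 0.384 each. The muscle list had 1 of 18 in replicate 1 alone and 2 of 18 in replicate 2 alone, where the exact upper limit was 34.7%. The neuron list had 3 of 22, rgef-1 (pooled rank 1537), snb-1 (rank 2035) and egl-21 (rank 2048; exact adjusted p = 0.883). Germ granule and germline RNA regulators had 1 of 25, the RNA helicase gene cgh-1 (rank 56; exact adjusted p = 0.488), and meiosis genes 2 of 24, rad-51 (rank 1455) and him-17 (rank 2146; adjusted p = 1). The him-17 peak ranked 3565 in replicate 1 and overlapped no entry of replicate 2, so it was not a site shared by the replicates. The snb-1 peak ranked 4322 in replicate 1 and 1313 in replicate 2. Small RNA pathway genes had 6 of 29, led by nrde-2 (rank 236, shared with atad-3), rde-4 (rank 290, shared with cox-14), rde-2 (rank 573, shared with pfd-6) and ekl-1 (rank 751, shared with prpf-4; odds ratio 2.00, exact adjusted p = 0.278). That list passed the threshold in replicate 2 alone (8 of 29, exact adjusted p = 0.0390) and with the stronger 1520 peaks (6 of 29, adjusted p = 0.0485). X dosage compensation and sex determination genes had 2 of 18, mix-1 (rank 2153, shared with R06F6.12) and dpy-30 (rank 2639; exact adjusted p = 1). That list had 1 of 18 in replicate 1 alone (odds ratio 0.453) and 4 of 18 in replicate 2 alone (odds ratio 2.24, exact adjusted p = 0.250). Other small lists also moved: germ granule genes had 2 of 25 and meiosis genes 1 of 24 in replicate 2 alone, and neuron genes had 2 of 22 and vulval induction genes 2 of 16 in replicate 1 alone. The mix-1 peak ranked 3602 in replicate 1 and 2021 in replicate 2.

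**Figure D5:**
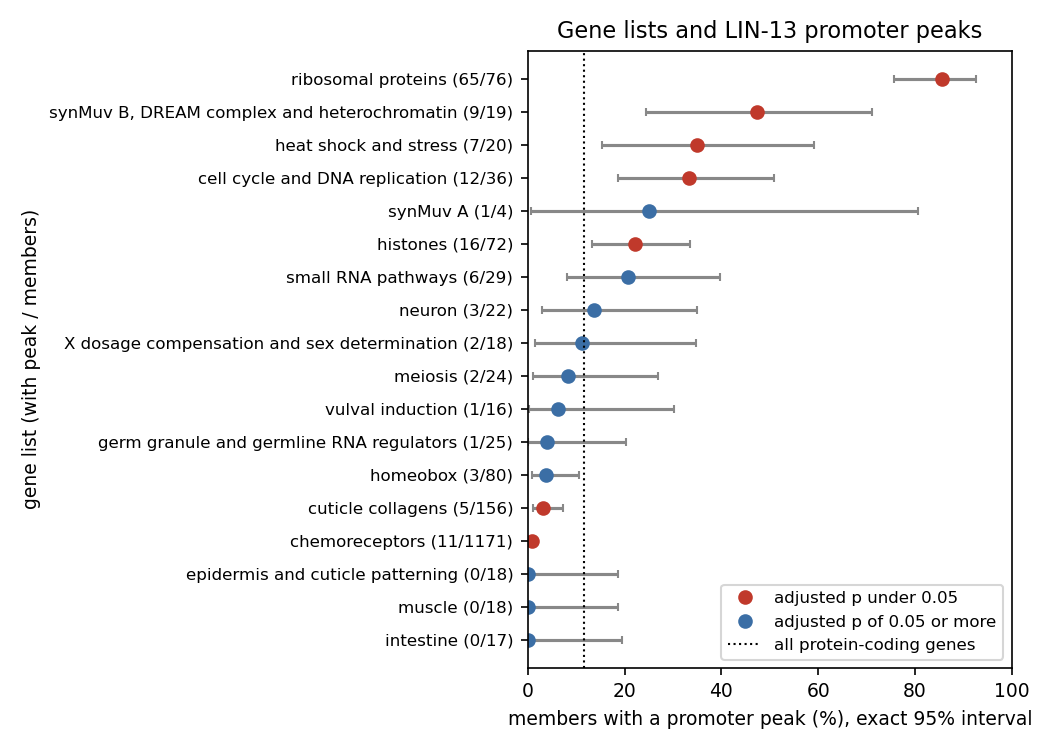
Share of each list's members with a thresholded summit in the promoter window (x axis, %, points with exact 95% intervals) for 18 gene lists (y axis, with counts), and the share over all protein-coding genes (dotted line). Ribosomal proteins lie at 85.5% and chemoreceptors at 0.939%, with all protein-coding genes at 11.6%.

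Short sequence motifs were compared between the 151 bp around each nuclear summit and a window 500 bp away. GAGAGA occurred at 35.7% of summits and in 8.56% of control windows (989 peaks had it at the summit only and 172 in the control only; exact McNemar test, two-sided, p = 8.24e-140, adjusted p = 3.71e-139). TTSSCGC, the form bound by E2F proteins, occurred at 13.6% against 4.98% (exact adjusted p = 6.55e-31), TGTTTAY, the forkhead form, at 6.94% against 4.35% (adjusted p = 1.97e-05), and the E-box CACGTG at 5.38% against 3.02% (adjusted p = 1.01e-05). Lower at summits were TTYGAA (35.1% against 43.3%, exact adjusted p = 1.66e-10), TTTTTTTT (9.39% against 16.06%, adjusted p = 1.02e-14) and the GATA form WGATAR (23.5% against 27.2%, adjusted p = 0.000901), whereas TGACTCA gave 1.36% against 1.66% (adjusted p = 0.397). In the 1727 promoter peaks, a split chosen after the data were seen, TTYGAA was not lower (40.5% against 39.3%, exact adjusted p = 0.566). Mean GC content was 43.7% at summits and 36.5% in control windows, and it was higher at the summit for 2189 peaks and lower for 771 (exact sign test, two-sided, adjusted p = 8.40e-155).

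Composition differed between summits and control windows, so the 7 motifs with a distinct rearrangement, all but TTTTTTTT, were also set against rearranged versions of themselves, a comparison chosen after the data were seen. For GAGAGA the ratio of shares was 4.17, and 1 of 19 rearrangements, AGAGAG, which overlaps it, reached that value. Of 100 rearrangements of TGTTTAY, 0 reached its ratio of 1.595 (highest 1.14), whereas 14 of 100 did for TTSSCGC (ratio 2.73) and 27 of 100 for CACGTG (ratio 1.78). Among the motifs with lower shares at summits, 14 of 100 rearrangements of TTYGAA lay at or above its ratio of 0.810 (median 0.676), 36 of 100 for WGATAR (0.863, median 0.811) and 43 of 100 for TGACTCA (0.820, median 0.749), so most rearrangements were lower still. The TGTTTAY call was lost in replicate 1 alone (6.17% against 5.64%, exact adjusted p = 0.410) and with the stronger 1520 peaks (adjusted p = 0.258). The CACGTG call was also lost with those stronger peaks (exact adjusted p = 0.0694) and in peaks in promoters (adjusted p = 0.156). The WGATAR call was lost with 150 bp on each side (exact adjusted p = 0.504) and in peaks outside promoters (adjusted p = 0.433). With 50 bp on each side, TGACTCA was lower at summits (0.597% against 1.29%, exact adjusted p = 0.00751).

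The ce10 lists gave 3033 thresholded peaks against 3040 on ce11, with the same chromosome counts for I (554), V (420), X (500) and the mitochondrial chromosome (27). In the ce10 lists 2179 thresholded peaks overlapped the strongest entries of both replicates (71.8%), the signal correlation was rho = 0.70, and X held 16.6% of nuclear peaks.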

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

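Of the tests in this part, the GC stratification was set out before its value was seen; the others were chosen after the results they concern were seen. No biological explanation was tested, since the design holds a single group.

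The mitochondrial chromosome, which none of the nuclear comparisons used, carried 27 thresholded peaks, of which 13 were among the 20 strongest of all. The strongest, at 4390-4947 on the mitochondrial chromosome, ranked 1 in each replicate and in the pooled list. Thresholded peaks covered 61.4% of this chromosome's 13794 bp, against 0.964% of nuclear sequence, which is consistent with an excess of mitochondrial DNA in the immunoprecipitates over the control. That 1 replicate alone was the source of every mitochondrial peak is argued against by 8 mitochondrial entries among the 3040 strongest of replicate 1 (exact binomial p = 1.59e-08 against this chromosome's share of the genome), which covered 16.7% of it against 79.9% for the 28 entries of replicate 2. Replicate 2 alone as the source of part of the peaks stays open, with 19 of 27 that overlapped an entry of replicate 2 and none of replicate 1, against 7 of 3013 nuclear peaks (Fisher's exact p = 1.24e-37), as do binding inside mitochondria and how the control was matched. The binomial and Fisher tests counted mitochondrial entries as independent, although they lie close together on 1 chromosome and some share an interval. Their p values therefore overstate the evidence.

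The high share of ribosomal protein promoters (65 of 76) was weighed against base composition. Among genes with a pooled entry at the promoter, the share with a thresholded peak was 7.24% in the lowest GC tercile, 28.7% in the middle and 58.0% in the highest, so GC content of the promoter could account for part of the list results. Stratified by tercile, the ribosomal protein odds ratio was 11.6 (95% interval 4.68 to 28.6), against 23.8 without strata. This argues against GC tercile as the whole cause. In the highest tercile lay 60 ribosomal protein genes, of which 56 had a peak, against 1376 of 2411 other genes. GC differences within a tercile were not adjusted for and stay open. A signal that follows transcript output, activity in most cells against dilution of tissue-restricted genes, and general accessibility of such promoters stay open, because expression and other proteins' peaks were not analysed here.

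Extra transgene copies could raise reads across lin-13, and across unc-119 if the marker is the C. elegans gene, which the labels do not say. Inside unc-119 there were 7 pooled entries, and 4.44% of 1621 genes of like length held as many or more, so extra copies of unc-119 sequence stay possible under that condition only. Inside lin-13 there were 0, and 28.3% of 996 genes of like length held as few, so extra copies of lin-13 as a source of the upstream peaks cannot be told apart from enrichment at the endogenous site: broad excess does not have to yield peak entries. The labels do not say how many copies the strain carries.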

How the results depend on the processing

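Alternatives chosen after seeing the data were leaving out mitochondrial peaks, keeping 1 summit per interval, the nearest start only and the split of motif tests by promoter. Of 57 alternative values for the main results, 52 kept their direction and side of the threshold or stayed within the allowed range, and 0 reversed. The arm share passed the threshold in replicate 2 alone (range 50.7% to 51.4% over the replicates taken alone, against 54.2% and 52.1% of their other entries). The soft-masked share lost its call in the shift test when any masked base counted (88.98%), though not against the other pooled entries (odds ratio 0.419). The lists past the threshold numbered 7 and fell to 4 among genes with a pooled entry at the promoter and to 4 with the nearest start only, all 4 among the original 7 in each case. The best pooled rank near unc-119 became 1805 within 20000 bp, at another entry. Peaks shared with both replicates numbered 1889 when 50% of both intervals had to overlap and 2056 with summits within 100 bp. Of 162 values for single lists 11 lost and 4 gained a call, and of 90 for single motifs 6 lost and 1 gained one. Apart from these, the TTYGAA ratio in peaks in promoters was 1.05 in place of 0.710. It passed no threshold there (exact adjusted p = 0.566), so a difference in the opposite direction was not shown. The top of the pooled list is the thresholded list itself, so that alternative moved nothing. Keeping 1 summit per interval left 3010 of 3013 nuclear peaks, so it could move little. Values of these alternatives are among the 52. Unless stated, the cause was not tested. Depth is unknown, so its effect on weak peaks was not tested.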

Other observations

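All tests in this part were chosen after the data were seen. Groups of at least 12 genes were scanned, 145 in all, each sharing a name prefix apart from a merged group of proteasome subunits, with two-sided Fisher's exact tests adjusted over the groups. Promoter peaks were more frequent in 23 groups and less frequent in 21, and the rpn genes entered both as their own group and in the merged one. Some of these groups repeat lists tested above, namely rps and rpl (ribosomal proteins), his (histones) and col (cuticle collagens). The groups with fewer peaks also include parts of the chemoreceptor list (srh, srw, srx, srg, srt, srbc, srd, sri and srz). Both counts therefore hold those earlier results again. Beyond the ribosomal proteins, proteasome subunits (pas, pbs, rpn and rpt genes) had peaks at 18 of 33 members (odds ratio 9.23, 95% interval 4.39 to 19.7, exact adjusted p = 8.79e-08), led by rpn-3 (pooled rank 95, at a promoter shared with hsp-110) and pbs-1 (rank 310, shared with K08D12.3). Mitochondrial ribosomal proteins of the mrpl family had 18 of 41 (odds ratio 6.02, exact adjusted p = 3.91e-06), nuclear pore npp genes 13 of 26 (odds ratio 7.67, adjusted p = 2.83e-05), and vps genes of vacuolar sorting 13 of 31 (odds ratio 5.54, adjusted p = 0.000214). Cytochrome c oxidase cox genes had 8 of 15 (exact adjusted p = 0.000933), led by cox-5A (rank 21) and cox-5B (rank 45). With each summit given to the nearest start only, the counts were 15 for the proteasome, 10 each for mrpl, npp and vps, and 6 for cox. Peaks were scarce at C-type lectin clec genes (4 of 240, odds ratio 0.128, exact adjusted p = 3.10e-07), nuclear hormone receptor nhr genes (14 of 269, odds ratio 0.416, adjusted p = 0.00400) and neuropeptide-like nlp genes (1 of 71, odds ratio 0.109, adjusted p = 0.0135). Replicates taken alone gave npp genes 17 of 26 (replicate 1) and 10 of 26 (replicate 2), and nlp genes 2 of 71 in each. The other groups named here had 20 proteasome and 17 mrpl genes in each replicate, 14 vps and 8 cox genes in each, 5 and 3 clec genes, and 17 and 13 nhr genes.

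Non-coding genes were set against the same circular shifts, counting summits within 500 bp. Transfer RNA genes had 176 summits nearby against a mean of 16.97 (SD 4.19) after shifts, and 202 of 612 such genes (33.0%) had one. Small nucleolar RNA genes had 101 summits nearby against 11.9 (SD 3.51), small nuclear RNA genes 34 against 3.84 (SD 2.05) and microRNA genes 26 against 7.57 (SD 2.91). Pseudogenes had 49 against 140.7 (SD 13.7) and piRNA genes 65 against 131.8 (SD 13.4). Long intergenic non-coding RNA genes had 35 against 13.1 (SD 3.83). Each of these two-sided permutation p values was 0.001, the smallest possible, with an adjusted p of 0.00114 over 8 classes. Ribosomal RNA genes, the remaining class, had 0 summits nearby against 0.672 (SD 0.915; permutation p = 0.7243). Many transfer RNA and small nuclear RNA genes are near-identical copies, so which copy carried a peak is uncertain.

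GAGAGA occurred at 574 of 1286 summits outside promoters (44.6%, against 8.55% in their control windows) and at 501 of 1727 promoter summits (29.0%, against 8.40%). The odds ratio between these locations was 1.97 (95% interval 1.69 to 2.30, two-sided Fisher's exact p = 1.07e-18, adjusted p = 2.14e-18 over 2 motifs). TTSSCGC went the other way, at 122 of 1286 and 287 of 1727 summits (odds ratio 0.526, interval 0.416 to 0.662, exact adjusted p = 1.05e-08). Over 2066 unselected 6-base words present in at least 30 control windows, the highest summit-to-control ratios were those of ACGCGC (459 against 66 peaks), GACGCA (609 against 88) and GCGCGC (294 against 45), none of which was among the motifs fixed beforehand. Mean GC content was 43.7% at summits and 36.5% in control windows. These words were not set against rearrangements, so their ratios were not separated from base composition.

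Strong peaks also lay far from the outermost annotated starts of protein-coding genes. Other starts of the same genes and starts of non-coding genes were not considered. X:13700590-13701046, 6055 bp from the start of K02D3.1 and intergenic, ranked 16 in replicate 1 and 30 in replicate 2. III:1925227-1925415, in an intron and 18305 bp from the start of F53A3.1, ranked 183 and 204. X:5429435-5429655, 15200 bp from the start of C41A3.2 and in a coding exon, ranked 159 and 113.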
